A study of Brassica napus with 18 samples.

How the data were processed

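The series holds 18 RNA-seq libraries of Brassica napus aerial parts, 3 for each combination of genotype (WT, bnagrp3) and treatment (mock, 200 mM NaCl for 4 h, 200 mM NaCl for 8 h). The submitters' processing notes name fastp, HISAT2 and featureCounts, without versions. The genome build and annotation are not given in the sources used here, and no strand information is stated. The only deposited values are a table of TPM per gene and library, as TPM per the file headers, with a description of each gene; read counts and read depth are absent, so the precision that depth gives each library is unknown and was judged from the spread between replicates.

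The table has 108207 genes, of which 106575 carry a protein database description and 73956 a Swiss-Prot match (64760 to Arabidopsis thaliana). By identifier 44359 lie on A chromosomes, 52561 on C chromosomes and 3908 on scaffolds, and 7379 are unplaced gene models of the submitters. Genes reaching 1 TPM in at least 3 of the 18 samples were kept, which left 57923. Values were analysed as log2(TPM + 1), as deposited, without rescaling. A linear model with 1 mean per group was fitted to all 18 samples with limma 3.58.1 in R 4.3.3, with moderated t-tests and an intensity trend, and contrasts gave 12 comparisons: NaCl against mock at each time in each genotype, 8 h against 4 h in each genotype, bnagrp3 against WT in each treatment and on average, and the differences of the 4 h and 8 h responses. P-values were two-sided and adjusted by Benjamini-Hochberg over all genes kept, with a call at an adjusted p under 0.05. No covariate was used. Whether libraries with the same replicate number belong together is not stated, so they were not paired.

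Gene lists were written before the data were examined, 36 in number, and matched to the descriptions by product name or symbol. Symbols shared by unrelated products bring in some wrong members, which the text names where they lead a list. Lists with at least 5 genes were tested with camera in limma at its preset inter-gene correlation of 0.01, adjusted over lists and comparisons together, and again with a correlation estimated from the data. For each list the members called higher, lower or not called are counted, over all genes and with p-values adjusted over the list alone. Agreement between responses is a Pearson correlation across genes, beside 20 simulated sets of unchanged groups where mock libraries are shared. Subgenomes were compared with Fisher exact tests, which treat genes as independent, so their p-values measure no spread between libraries. The table was also searched for identical libraries.

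The rule for naming genes was fixed in advance: every GRP3 gene; of each list described, up to 2 members with the largest rise and 2 with the largest fall among called genes whose 3 libraries on one side all lie above or below the other 3 and whose mean reaches 5 TPM in a group; and the 5 largest rises and falls overall with a mean of at least 10 TPM. Unplaced gene models and genes without a known product were mostly left unnamed. Genes used to describe differences among WT libraries were chosen after values were seen: at least 5 TPM in all 9 bnagrp3 libraries and at most 0.2 TPM in at least 2 of 9 WT libraries. Their level in a WT library, as the median ratio to the bnagrp3 mean of the same treatment, is called the share.

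The procedure was tested on simulated data with the spread of these libraries. It recovered 75% of genes changed by 1 log2 unit and 94% of those changed by 2 units in the WT 4 h comparison, 71% and 93% in the mock genotype comparison, and 57% and 85% for the difference of the 4 h response, each with 100 genes changed per step, and made 13, 5 and 10 false calls. The changed genes were drawn from those with a mean log2(TPM + 1) above 2, so recovery of weaker genes is unknown. Each gene had the same simulated spread in every group, so false calls from a larger spread among WT libraries were not covered.

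Alternatives fixed before the data were examined were a pseudocount of 0.1, no filter, a filter of 5 TPM, median-of-ratios rescaling, quantile normalisation, a fit of only the groups compared, a replicate block, a further threshold of 1 log2 unit, an estimated inter-gene correlation and leaving out each library. Leaving out the 2 WT libraries of highest share, the share as a covariate and matching lists by product name only were chosen after seeing the data. As a covariate the share was set to 1 in bnagrp3, and the fit was repeated with 100 orders of the shares within WT groups, also after seeing the data. Counts of called genes were also compared with those from other splits of the same samples. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.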

Results

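Poly(A) RNA from the aerial part of Brassica napus seedlings was sequenced in 18 libraries, 3 in each of 6 groups. Wild type (WT) and a bnagrp3 mutant line were grown for 3 weeks in nutrient solution and sampled in mock or after 4 h or 8 h in 200 mM NaCl. The table holds TPM, which keeps no read depth, so depth is unknown. Mock libraries are headed 0 h in the table, so no mock matches the 4 h or the 8 h samples in time of day. The labels do not say that replicates come from separate plants, so each p-value measures only the spread between these libraries, which may be technical. Comparisons, lists and thresholds were chosen before the data were examined. Values are mean TPM ± SD (n = 3), and fold changes are log2 of TPM + 1, a scale that understates changes of weakly expressed genes. B. napus is an allotetraploid, and how reads shared by homeologs were divided is not stated.

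GRP3 genes encode small glycine-rich secreted proteins, in Arabidopsis a partner of wall-associated kinase 1. The labels do not say which copies are mutated. Transcripts of 3 of them were lower in the mutant in every condition. BnaA07G0050000ZS stood at 16.9 to 24.4 TPM in the 3 WT mock libraries and at 0.88 to 1.91 in the 3 bnagrp3 mock libraries. With NaCl its 6 WT libraries lay between 56.5 and 137, and its 6 bnagrp3 libraries between 3.22 and 11.2. BnaC07G0084100ZS lay at 4.73 to 39.6 TPM over the 9 WT libraries and at 0.17 to 5.95 over the 9 bnagrp3 libraries. An unplaced gene model with the same Swiss-Prot name lay at 376 to 2799 TPM in WT and at 0 to 4.51 in bnagrp3. A second description calls BnaC07G0084100ZS and BnaC07G0083900ZS CORA-like proteins. It calls the unplaced model, BnaC07G0084200ZS and Bnascaffold0025G0035900ZS dormancy-associated proteins. The most abundant pair, BnaA03G0387800ZS and BnaC03G0480300ZS, was lower in bnagrp3 by a smaller step, at 8 h 1679 ± 83.8 against 2436 ± 177 TPM and 2952 ± 100 against 4182 ± 207 TPM. With the WT level of other bnagrp3-type transcripts (the share described below) as a covariate, a test chosen after seeing the data, neither was called and their estimates turned to 0.036 and 0.13 in mock and 0.25 and 0.24 at 8 h. BnaA07G0050000ZS stayed called on average (-4.19, adjusted p = 1.28e-05).

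Fold changes for these genes followed the library values. BnaA07G0050000ZS was lower in bnagrp3 by a log2 fold change of -3.11 (SE 0.23, adjusted p = 2.25e-07) in mock, -3.98 (adjusted p = 1.13e-08) at 4 h and -3.64 (adjusted p = 2.87e-08) at 8 h. BnaA03G0387800ZS differed by -0.69 in mock (adjusted p = 0.00355) and -0.54 at 8 h (adjusted p = 0.0154), and was not called at 4 h (adjusted p = 0.0671). BnaA03G0387900ZS was not called in any genotype comparison (adjusted p = 0.551, 0.151 and 0.747). BnaC07G0084200ZS was lower in bnagrp3 mock (12.4 ± 2.67 against 2.91 ± 1.16 TPM, -1.80, adjusted p = 0.0091) and not called at 4 h or 8 h (adjusted p = 0.122 and 0.811), though with the share as a covariate it was called lower at both (-2.88, adjusted p = 0.00627, and -2.42, adjusted p = 0.0421). BnaC03G0480200ZS was lower at 4 h (4.57 ± 1.4 against 0.93 ± 0.84 TPM, -1.61, adjusted p = 0.02; -1.36, adjusted p = 0.48 with the covariate), and not called in mock or at 8 h (adjusted p = 0.793 and 0.628). BnaC03G0480400ZS (adjusted p = 0.245, 0.654 and 0.635) and BnaC07G0083900ZS (0.249, 0.599 and 0.533) were not called in mock, at 4 h or at 8 h. Bnascaffold0025G0035900ZS went the other way, at 2.24 ± 1.2, 4.00 ± 2.63 and 4.38 ± 0.998 TPM in WT mock, 4 h and 8 h and 6.96 ± 0.78, 38.4 ± 10.4 and 143 ± 19.6 TPM in bnagrp3. Of 14 genes with the name, 11 reached the minimum level for testing. Of these 11, NaCl raised 5 in WT at 4 h and 9 at 8 h, and 7 and 11 in bnagrp3, and none fell.

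**Figure D1:**
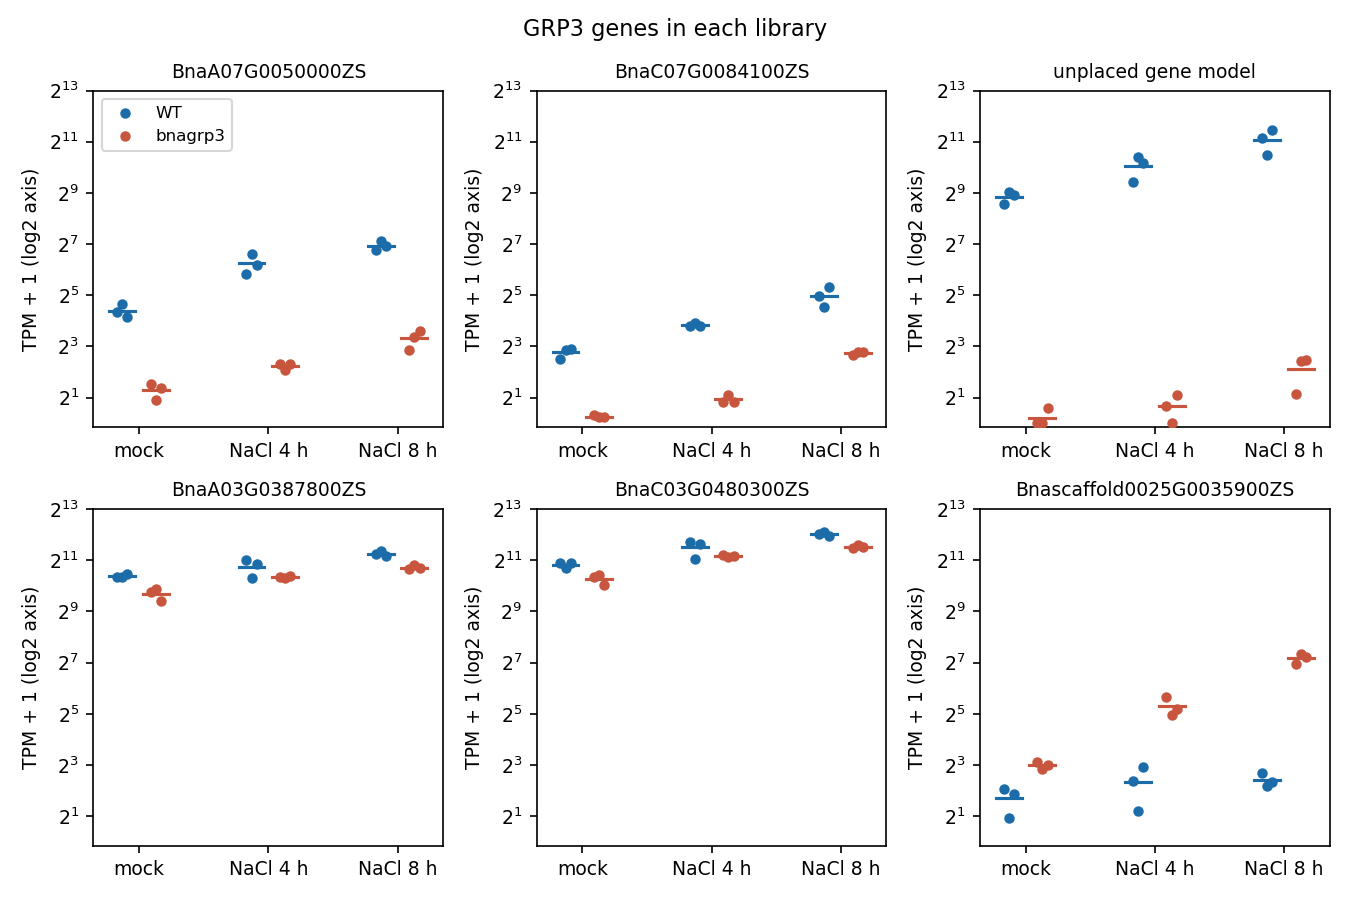
TPM + 1 (log2 axis) of 6 GRP3 genes in each of the 18 libraries, by treatment. Points are libraries and bars are group means. BnaA07G0050000ZS, BnaC07G0084100ZS and the unplaced gene model are far lower in bnagrp3, and Bnascaffold0025G0035900ZS is higher.

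Mock and NaCl libraries separated on the first principal component, and the genotypes on the second. WT libraries at 4 h and 8 h overlapped on both, on the second from 26.48 to 123.26 at 4 h and from 58.48 to 127.71 at 8 h. The first component held 36.8% of the variance and the second 28.78%. Correlations between replicates within a group ran from 0.888 to 0.958. The 3 WT libraries at 4 h had the lowest range of mean correlation with their own group (0.912 to 0.937), while bnagrp3 libraries stood at 0.954 to 0.958. No pair of libraries was identical. The number of genes above 0 ran from 63891 to 67072.

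WT libraries differed from one another in transcripts that every bnagrp3 library carried. A set of 326 genes, chosen after values were seen, reached 5 TPM in all 9 bnagrp3 libraries and lay at or under 0.2 TPM in 2 or more WT libraries. Relative to the bnagrp3 group of the same treatment, their median level was 0.231, 0.254 and 0.214 in the WT mock libraries. At 4 h it was 0, 0.67 and 0.233 in replicates 1, 2 and 3, and at 8 h it was 0.168, 0 and 0.369. The values of 0 partly follow from how the genes were chosen. Of the 326 genes, 72 lie on chromosome A09, 34 on C04 and 116 are not placed on a chromosome.

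This level is called the share. As a covariate it was set to 1 in bnagrp3, so it is partly confounded with genotype, and genotype estimates made with it are extrapolated. Of 100 orders of the shares within WT groups 63 gave as few calls for the average genotype difference as the real order, so the loss of a call with the covariate tells little of a gene. Estimates of responses within bnagrp3 cannot change, since the share is 1 throughout. In WT the mean shares lay close (0.233 in mock and 0.301 at 4 h), so response estimates can move little. That 26653 of the 26965 calls in WT at 4 h were kept therefore tells little of the background.

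**Figure D2:**
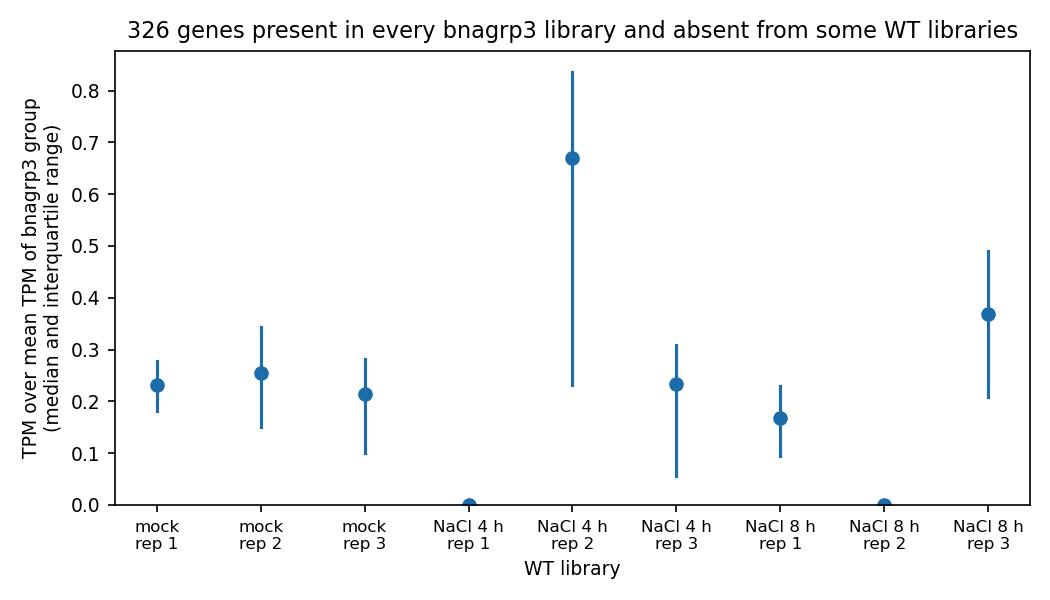
Level of 326 genes in each WT library, as TPM divided by the mean TPM of the bnagrp3 group of the same treatment. Points are medians and lines the interquartile range. WT 4 h replicate 2 stands highest (0.67), and WT 4 h replicate 1 and WT 8 h replicate 2 stand at 0.

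In WT at 4 h of NaCl the dehydrin gene RAB18 (BnaC02G0556300ZS), which responds to abscisic acid (ABA), rose from 0.61 ± 0.34 to 1598 ± 362 TPM, a log2 fold change of 9.95 (SE 0.28, adjusted p = 2.0e-12). KIN2 (BnaA03G0287800ZS) was listed at 0 in mock and reached 570 ± 34 TPM. P5CSA, whose enzyme opens proline synthesis, rose from 12.4 ± 1.14 to 580 ± 102 TPM (BnaA05G0063500ZS, 5.43) and from 20.8 ± 3.05 to 880 ± 22.5 TPM (BnaC04G0069800ZS, 5.34). Rubisco small-subunit genes fell, RBCS-3B (BnaA07G0167600ZS) from 553 ± 155 to 41.3 ± 13.1 TPM (-3.72) and RBCS (BnaC06G0156800ZS) from 1590 ± 357 to 155 ± 12.2 TPM (-3.32).

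Late embryogenesis abundant (LEA) proteins and dehydrins formed the clearest rise. Of 92 tested genes 68 rose, 0 fell and 24 were not called; adjusted over the list alone, 71 rose and 0 fell (median 2.00, adjusted p = 2.52e-22). RAB18 (BnaA02G0419400ZS, 8.80) and LEA46 (BnaC09G0580800ZS, 8.25) were among them, LEA46 with 391 ± 100 TPM at 4 h. ABA synthesis and breakdown followed, with 24 of 36 genes risen, 3 fallen and 9 not called (26 and 5 adjusted over the list alone, median 0.87, adjusted p = 3.5e-06). NCED3, the step that limits ABA synthesis, rose from 1.16 ± 0.11 to 69.5 ± 12.8 TPM (BnaC05G0457600ZS, 5.01) and from 2.16 ± 0.39 to 84.7 ± 15 TPM (BnaA01G0353200ZS, 4.75). ABA4 (BnaA02G0163600ZS) fell from 37 ± 1.76 to 20.4 ± 1.23 TPM (-0.83, adjusted p = 8.9e-05).

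ABA signalling rose as a list, with 65 of 112 genes up, 17 down and 30 not called (66 and 19 adjusted over the list alone, median 0.52, adjusted p = 5.72e-08; adjusted p = 0.0957 with an estimated correlation). The phosphatase gene SAG113 rose to 74.6 ± 1.87 TPM (BnaA10G0146400ZS, 6.09) and 61.1 ± 6.85 TPM (BnaC09G0425100ZS, 5.93), while the receptor genes PYL4 (BnaA04G0246400ZS, -2.32) and PYL8 (BnaA03G0132000ZS, -1.76) fell. Proline metabolism had 17 of 33 genes up, 5 down and 11 not called, the same when adjusted over the list alone (median 0.42, adjusted p = 0.00287; adjusted p = 0.121 with an estimated correlation). Proline transporter gene PROT1 (BnaA03G0194900ZS) fell from 5.17 ± 0.27 to 0.67 ± 0.62 TPM (-1.95).

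NAC factors, many of them known from drought and senescence, had 99 of 210 genes up, 14 down and 97 not called (107 and 15 adjusted over the list alone, median 0.46, adjusted p = 4.36e-06; adjusted p = 0.15 with an estimated correlation). NAC019 rose to 80.0 ± 11.1 TPM (BnaC06G0072100ZS, 4.85) and 51.4 ± 6.94 TPM (BnaA06G0016000ZS, 4.68), and NAC035 (BnaA06G0402800ZS, -1.23) fell. Jasmonate synthesis and signalling had 53 of 104 genes up, 10 down and 41 not called (55 and 12 adjusted over the list alone, median 0.61, adjusted p = 0.00479; adjusted p = 0.61 with an estimated correlation), a call that ended when 1 library was left out (adjusted p = 0.0602). AOC2 rose from 0.52 ± 0.36 to 11.1 ± 3.17 TPM (BnaA06G0393700ZS, 2.98), and OPR1 (BnaC02G0300200ZS) fell from 12.3 ± 3.05 to 2.13 ± 0.60 TPM (-2.08). Raffinose, trehalose and starch breakdown was not called as a list (50 up, 28 down, 36 not called, 53 and 28 adjusted over the list alone, median 0.26, adjusted p = 0.107), but was with members matched by product name only (median 0.44, adjusted p = 0.0266), a test chosen after seeing the data that leaves out terpenoid synthases (TPS) and receptor kinases (BAM). Galactinol synthase gene GOLS2 (BnaC09G0202600ZS) still rose from 2.75 ± 0.33 to 214 ± 9.52 TPM (5.84), and TPPA (BnaA02G0149500ZS, -2.12) fell.

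Photosynthesis and Rubisco genes fell, with 148 of 210 down, 9 up and 53 not called (152 and 10 adjusted over the list alone, median -0.58, adjusted p = 5.48e-21; adjusted p = 0.0832 with an estimated correlation). The 2 largest rises in that list, BnaA09G0482600ZS and BnaC08G0318900ZS, are prosaposin genes matched by the symbol PSAP and not photosystem genes. Organelle-type genes, a list matched by symbol only, fell in 64 of 177, with 6 up and 107 not called, the same adjusted over the list alone (median -0.37, adjusted p = 1.36e-05); ndhT (BnaA09G0262100ZS, -2.02) fell and rplB (BnaA04G0280100ZS, 1.01) rose, and these 2 lie on nuclear chromosomes. Cytosolic ribosomal protein genes fell in 616 of 1037 cases, with 38 up and 383 not called (633 and 44 adjusted over the list alone, median -0.61, adjusted p = 5.63e-16; adjusted p = 0.302 with an estimated correlation). RPS30A (BnaC02G0151300ZS) fell from 81.2 ± 10.4 to 22.7 ± 23.1 TPM (-2.99, SE 1.03, adjusted p = 0.028), while a gene for an L18a-like protein (BnaC06G0078500ZS) rose from 17.9 ± 3.06 to 74.1 ± 6.28 TPM (2.00). Nitrate uptake and assimilation fell in 25 of 45 genes, with 10 up and 10 not called, the same adjusted over the list alone (median -0.48, adjusted p = 0.00241; adjusted p = 0.216 with an estimated correlation). Nitrite reductase gene NIR1 (BnaA09G0107500ZS) fell from 124 ± 16.3 to 18.2 ± 1.66 TPM (-2.70), and glutamine synthetase genes split, GLN1-3 (BnaA05G0381200ZS) up by 2.51 and GLN1-4 (BnaC02G0075000ZS) down (-2.47).

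Cell wall synthesis and pectin genes fell in 202 of 478, with 77 up and 199 not called (204 and 77 adjusted over the list alone, median -0.39, adjusted p = 1.05e-06). Arabinogalactan protein genes split, AGP5 (BnaC03G0296500ZS) up by 4.45 and AGP12 (BnaA06G0004900ZS, -4.78, SE 1.65, adjusted p = 0.0273) down. Cell wall loosening genes moved both ways and were not called as a list (39 up, 51 down, 52 not called of 142, 40 and 52 adjusted over the list alone, median -0.22, adjusted p = 0.0909). Expansin-like gene EXLB1 (BnaC01G0231200ZS) rose from 0.07 ± 0.13 to 130 ± 49.8 TPM (6.85), and the growth-associated expansins EXPA1 (BnaA02G0182000ZS, -3.64) and EXPA8 (BnaC03G0233800ZS, -3.29) fell. Among the largest falls of all genes was germin-like GER1 (BnaA07G0334400ZS), from 552 ± 205 to 11.2 ± 2.25 TPM (-5.45). In all, 26965 of 57923 genes were called at an adjusted p under 0.05, 15078 higher and 11887 lower (55.9% higher, and 49.2% after median-of-ratios rescaling), and 8877 changed at least 2-fold. With only these groups in the fit 20668 were called. Shares of called genes did not differ between the A and C subgenomes (odds ratio 0.995, adjusted p = 0.776), but did without the filter on low values (1.048, unadjusted Fisher exact p = 0.00249).

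At 8 h in WT RAB18 stood at 1685 ± 90.8 TPM (BnaC02G0556300ZS, 10.05), and a more abundant copy (BnaA09G0101100ZS) went from 31.3 ± 2.70 to 10200 ± 399 TPM (8.31). The vacuolar aquaporin gene TIP2-1 (BnaA03G0345300ZS) fell from 144 ± 17 to 4.75 ± 0.76 TPM (-4.66, SE 0.17, adjusted p = 3.9e-11), and TIP1-1 (BnaA04G0236300ZS) from 229 ± 50.3 to 14.0 ± 1.67 TPM (-3.92). XTH6, for a wall-remodelling enzyme, fell from 182 ± 21.1 to 3.26 ± 0.84 TPM (BnaC03G0517900ZS, -5.43). Nitrate reductase gene NIA2 (BnaA07G0237900ZS) fell from 69.5 ± 2.88 to 4.09 ± 1.24 TPM (-3.82).

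LEA proteins and dehydrins again rose in 67 of 92 genes, with 1 down and 24 not called, the same adjusted over the list alone (median 1.82, adjusted p = 1.91e-17). The 1 that fell (BnaC03G0253900ZS, -0.59) went from 7.94 ± 0.25 to 4.94 ± 0.46 TPM. ABA signalling had 65 up, 21 down and 26 not called of 112 (67 and 23 adjusted over the list alone, median 0.57, adjusted p = 1.98e-06; adjusted p = 0.134 with an estimated correlation), with SAG113 (BnaA10G0146400ZS) at 5.51 and PYL4 (BnaA04G0246400ZS) at -2.40. Proline metabolism had 17 up, 5 down and 11 not called of 33, the same adjusted over the list alone (median 0.44, adjusted p = 0.0324; adjusted p = 0.213 with an estimated correlation). P5CSA stayed high (BnaA05G0063500ZS, 517 ± 10.4 TPM) and PROT1 (BnaA03G0194900ZS, -2.15) low.

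Photosynthesis and Rubisco genes fell in 152 of 210 cases, with 10 up and 48 not called (159 and 10 adjusted over the list alone, median -0.73, adjusted p = 5.8e-29), and the organelle-type list in 41 of 177, with 20 up and 116 not called (39 and 20 adjusted over the list alone, median -0.07, adjusted p = 0.0115; adjusted p = 0.155 with an estimated correlation). Cell wall synthesis and pectin genes fell in 230 of 478, with 61 up and 187 not called (235 and 66 adjusted over the list alone, median -0.47, adjusted p = 1.22e-11). The aquaporin list fell in 51 of 112 genes and rose in 35, with 26 not called (54 and 36 adjusted over the list alone, median -0.35, adjusted p = 0.000573; adjusted p = 0.134 with an estimated correlation). Its symbols also match PIP5K kinases, secreted PIP peptides and NEP1-interacting proteins, and the 85 genes matched by product name had a median of -0.71 (adjusted p = 5.59e-08). PIP2-5 (BnaA09G0506600ZS, 2.01) and SIP2-1 (BnaC04G0304400ZS, 1.88) were the largest rises there, to 10.7 ± 2.96 and 12.5 ± 1.38 TPM. Cell wall loosening fell in 62 of 142 genes and rose in 34, with 46 not called (63 and 34 adjusted over the list alone, median -0.39, adjusted p = 4.6e-05), with EXLB1 (BnaC01G0231200ZS) still up at 200 ± 19.9 TPM (7.55).

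Glucosinolate synthesis fell in 31 of 67 genes and rose in 4, with 32 not called, the same adjusted over the list alone (median -0.56, adjusted p = 1.05e-06; adjusted p = 0.267 with an estimated correlation). IGMT4 (BnaA07G0239100ZS), for an indole glucosinolate methyltransferase, fell from 14.1 ± 2.04 to 1.26 ± 0.16 TPM (-2.73), and SOT18 (BnaC09G0197100ZS, 2.14) rose. Nitrate uptake and assimilation fell in 20 of 45 genes and rose in 11, with 14 not called, the same adjusted over the list alone (median -0.36, adjusted p = 0.000385; adjusted p = 0.154 with an estimated correlation). NRT3.1 (BnaA02G0153500ZS, 2.30) rose to 6.97 ± 1.43 TPM. Cell division genes fell in 146 of 308 and rose in 47, with 115 not called (148 and 49 adjusted over the list alone, median -0.36, adjusted p = 1.02e-07). An H4 histone gene (BnaC03G0608200ZS) fell from 18.4 ± 2.64 to 1.96 ± 1.74 TPM (-2.89), and the H2A gene RAT5 (BnaA10G0108500ZS) rose from 2.10 ± 0.52 to 29.2 ± 3.82 TPM (3.29).

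At 8 h in WT 26826 genes were called (23171 with only these groups in the fit), 16786 higher and 10040 lower, and 8607 changed at least 2-fold. The median of all genes shifted by 0.14 at 8 h in each genotype, and 62.6% of called genes were higher in WT. After median-of-ratios rescaling that share was 49.5%. Such rescaling brings the median of all genes near 0 (0.006 here), so a near-even split follows largely by construction. The balance of rises and falls thus depends on the scaling chosen, and the rescaled values do not test it.

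In bnagrp3 at 4 h KIN2 (BnaA03G0287800ZS) was listed at 0 in mock and reached 526 ± 83.9 TPM, and LEA46 (BnaC09G0580800ZS) rose from 0.62 ± 0.51 to 451 ± 57.1 TPM (8.16, SE 0.27, adjusted p = 1.2e-11). RAB18 (BnaC02G0556300ZS) reached 308 ± 115 TPM (7.60). NCED3 rose to 62.9 ± 0.42 TPM (BnaC01G0439400ZS, 4.39) and 31.4 ± 3.46 TPM (BnaA05G0407000ZS, 4.25). Pectin methylesterase gene PME3 (BnaC01G0440300ZS), which acts on wall pectin, fell from 56 ± 12.7 to 0.95 ± 0.14 TPM (-4.85).

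LEA proteins and dehydrins rose in 63 of 92 genes, with 1 down and 28 not called (65 and 1 adjusted over the list alone, median 1.62, adjusted p = 1.73e-15). ABA synthesis and breakdown rose in 22 of 36, with 3 down and 11 not called (24 and 3 adjusted over the list alone, median 0.72, adjusted p = 4.98e-05); ABA4 (BnaC02G0209500ZS, -1.18) fell. NAC factors rose in 108 of 210, with 15 down and 87 not called (113 and 15 adjusted over the list alone, median 0.45, adjusted p = 3.97e-06; adjusted p = 0.15 with an estimated correlation). NAC019 (BnaC06G0072100ZS) reached 106 ± 4.60 TPM (5.87), and NAC083 (BnaA10G0082500ZS, -1.47) fell. Raffinose, trehalose and starch breakdown rose in 56 of 114, with 27 down and 31 not called (56 and 28 adjusted over the list alone, median 0.56, adjusted p = 0.0175; adjusted p = 0.15 with an estimated correlation). The 77 matched by product name, without terpenoid synthases and BAM receptor kinases, had a median of 0.56 (adjusted p = 0.00615). GOLS2 (BnaC09G0202600ZS) rose from 1.72 ± 0.63 to 189 ± 16.8 TPM (6.15), and the plastid beta-amylase gene BAM3 (BnaC07G0413500ZS, -1.97) fell.

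Jasmonate genes rose in 66 of 104, with 8 down and 30 not called (67 and 9 adjusted over the list alone, median 0.89, adjusted p = 1.23e-05; adjusted p = 0.415 with an estimated correlation). AOC2 (BnaC07G0290700ZS, 3.50) rose to 12.6 ± 7.13 TPM, and OPR1 (BnaA02G0222800ZS, -2.42) fell. Photosynthesis and Rubisco genes fell in 152 of 210, with 7 up and 51 not called (154 and 9 adjusted over the list alone, median -0.64, adjusted p = 5.48e-21; adjusted p = 0.0832 with an estimated correlation), RBCS (BnaC06G0156800ZS) to 135 ± 5.75 TPM (-3.41). The organelle-type list fell in 73 of 177, with 3 up and 101 not called (72 and 2 adjusted over the list alone, median -0.24, adjusted p = 2.36e-05). Cell wall synthesis and pectin genes fell in 230 of 478, with 75 up and 173 not called (240 and 79 adjusted over the list alone, median -0.45, adjusted p = 7.39e-07). CSLA10 (BnaA07G0112700ZS), for a mannan synthase, rose from 0.50 ± 0.10 to 19.7 ± 4.69 TPM (3.76). Cytosolic ribosomal protein genes fell in 789 of 1037, with 31 up and 217 not called (802 and 34 adjusted over the list alone, median -1.14, adjusted p = 3.71e-28; adjusted p = 0.15 with an estimated correlation), RPL39A (BnaC08G0427500ZS) from 131 ± 26.7 to 20.6 ± 19.3 TPM (-3.73, SE 1.36). GER1 (BnaA07G0334400ZS, -5.64) and defensin-like AFP3 (BnaC02G0290500ZS, -5.11) were among the largest falls. In all 30248 genes were called, 16636 higher and 13612 lower (55% higher, and 49.7% after rescaling), and 11684 changed at least 2-fold.

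At 8 h in bnagrp3 LEA46 (BnaC09G0580800ZS) reached 932 ± 88.0 TPM (9.21, SE 0.27, adjusted p = 3.5e-12). The ABA-pathway phosphatase gene AIP1 (BnaC05G0053800ZS) rose from 0.26 ± 0.03 to 70.9 ± 2.88 TPM (5.84). Glutaredoxin gene GRXS11 (Bnascaffold0026G0072400ZS) fell from 106 ± 19.7 to 0.36 ± 0.63 TPM (-6.38), and AFP3 (BnaC02G0290500ZS) from 126 ± 20.6 to 0.69 ± 1.19 TPM (-6.43). RPL39A (BnaC08G0427500ZS) was listed at 0.

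LEA proteins and dehydrins rose in 64 of 92, with 1 down and 27 not called, the same adjusted over the list alone (median 1.63, adjusted p = 5.63e-16). ABA signalling rose in 67 of 112, with 20 down and 25 not called (67 and 21 adjusted over the list alone, median 0.79, adjusted p = 4.98e-07; adjusted p = 0.121 with an estimated correlation), SAG113 (BnaA10G0146400ZS) by 5.76, while PYL4 (BnaA04G0246400ZS, -2.85) fell. Proline metabolism was not called as a list (17 up, 6 down, 10 not called of 33, 18 and 6 adjusted over the list alone, median 0.47, adjusted p = 0.0539). P5CSA still rose (BnaA05G0063500ZS, 681 ± 16.8 TPM, 5.38), and PROT2 (BnaA04G0039200ZS, -0.96) fell. Photosynthesis and Rubisco genes fell in 154 of 210, with 7 up and 49 not called (158 and 9 adjusted over the list alone, median -0.66, adjusted p = 2.5e-28), the organelle-type list in 47 of 177, with 7 up and the rest not called (44 and 5 adjusted over the list alone, median -0.16, adjusted p = 8.04e-05), and cell wall synthesis and pectin genes in 214 of 478, with 82 up and 182 not called (218 and 83 adjusted over the list alone, median -0.34, adjusted p = 4.69e-08).

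Glucosinolate synthesis fell in 33 of 67, with 3 up and 31 not called, the same adjusted over the list alone (median -0.60, adjusted p = 1.3e-06; adjusted p = 0.273 with an estimated correlation), IGMT4 (BnaA07G0239100ZS) by -3.21 and IGMT1 (BnaC07G0228500ZS) by -2.96. Nitrate uptake and assimilation fell in 22 of 45, with 10 up and 13 not called (23 and 10 adjusted over the list alone, median -0.39, adjusted p = 0.000295; adjusted p = 0.15 with an estimated correlation). NIA1 (BnaA07G0369900ZS) fell from 61.0 ± 10.7 to 9.24 ± 0.70 TPM (-2.58). Cell division fell in 156 of 308, with 44 up and 108 not called (159 and 45 adjusted over the list alone, median -0.44, adjusted p = 1.22e-09). Histone gene HTR2 (BnaC08G0191300ZS) fell from 70.9 ± 15.1 to 8.93 ± 3.59 TPM (-2.89), and an H2A gene (BnaA02G0008200ZS, 1.47) rose. Cytosolic ribosomal protein genes fell in 731 of 1037, with 40 up and 266 not called (756 and 44 adjusted over the list alone, median -0.92, adjusted p = 3.97e-30; adjusted p = 0.15 with an estimated correlation), RPL17A (BnaA08G0220300ZS) to 1.78 ± 0.21 TPM (-2.67). In all 28782 genes were called, 18118 higher and 10664 lower, 62.9% and 49.3% higher before and after median-of-ratios rescaling, and 9827 changed at least 2-fold.

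**Figure D3:**
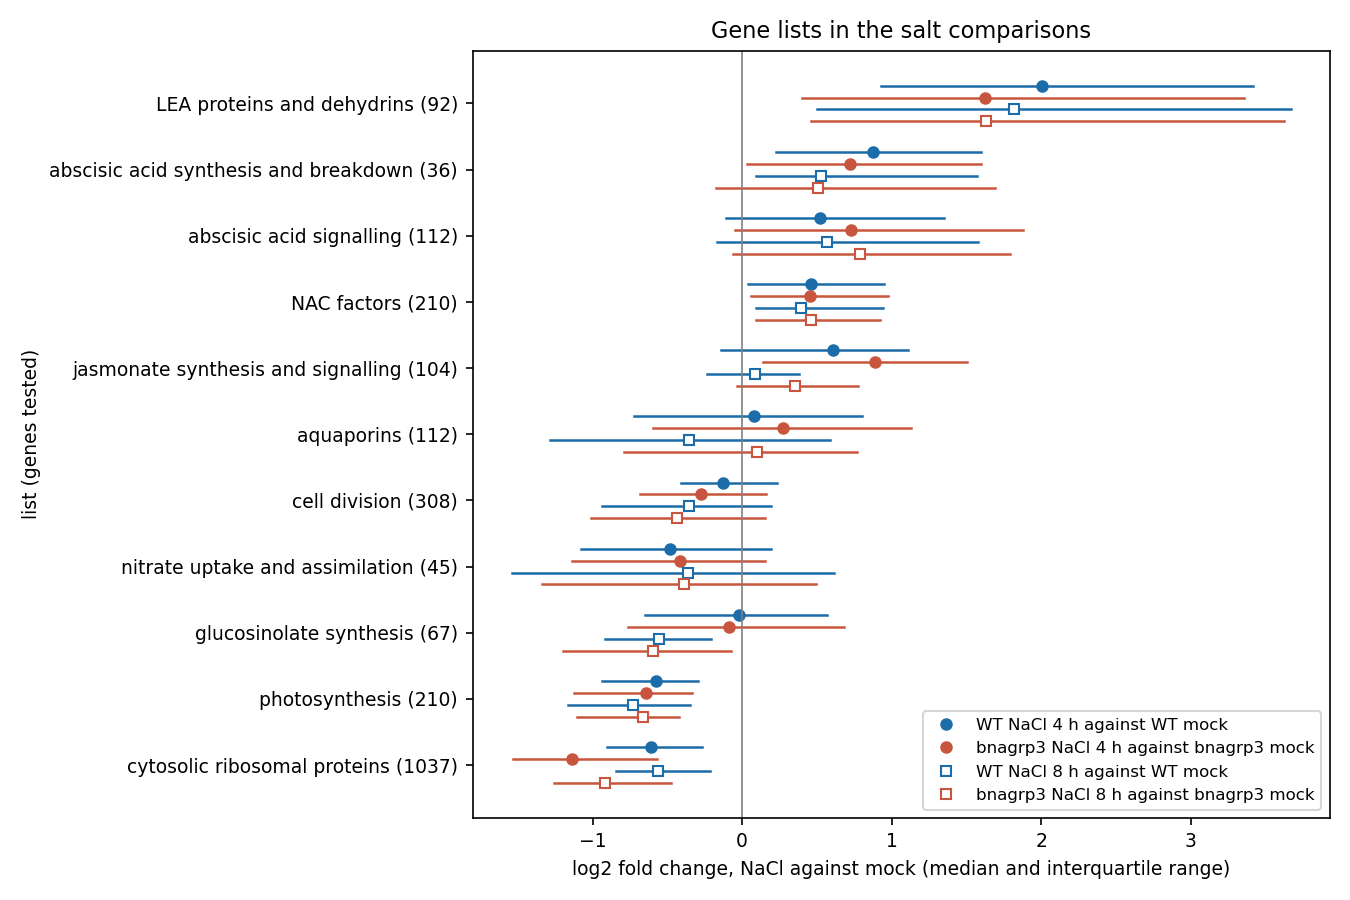
Median log2 fold change (points) and interquartile range (lines) of 11 gene lists, NaCl against mock, for WT and bnagrp3 at 4 h (filled circles) and 8 h (open squares). LEA proteins lie highest (medians 1.62 to 2.00), and ribosomal proteins in bnagrp3 at 4 h lie lowest (-1.14).

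RAB18, P5CSA and RBCS moved the same way in each genotype, and so did most called genes. Across all genes the log2 fold changes of WT and bnagrp3 correlated at 0.816 at 4 h and 0.819 at 8 h; genes are not independent replicates. At 4 h 12220 genes were higher in both (4330.54 would be shared by independent lists), 9672 lower in both (2793.46) and 112 went opposite ways. At 8 h these counts were 13538 (5250.57), 7827 (1848.43) and 84. Within a genotype 4 h and 8 h share their mock libraries, and 3 mocks are too few to split with 2 libraries in each part, so part of any excess may come from the shared controls. Their correlation was 0.860 in WT and 0.880 in bnagrp3, beside 0.499 and 0.5 simulated for unchanged groups, with covariances of 0.643 and 0.745 beside 0.0437 and 0.0430.

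Between 4 h and 8 h in WT AOC2 (BnaC07G0290700ZS) went from 12.6 ± 7.44 to 0.71 ± 0.19 TPM (-2.79, SE 0.45, adjusted p = 0.0011), and PIP2-2 (BnaA05G0081400ZS) from 112 ± 51.3 to 17.5 ± 2.38 TPM (-2.51). The H2A gene BnaC02G0123100ZS fell from 64.9 ± 19.2 to 14.2 ± 5.16 TPM (-2.13). Jasmonate genes fell in 38 of 104, with 6 up and 60 not called (45 and 8 adjusted over the list alone, median -0.45, adjusted p = 3.37e-09; adjusted p = 0.254 with an estimated correlation), while OPR1 (BnaC02G0300200ZS, 1.13) rose. The aquaporin list fell in 33 of 112 genes, with 7 up and 72 not called (37 and 7 adjusted over the list alone, median -0.20, adjusted p = 3.6e-08), with PIP2-6 (BnaC03G0223000ZS, 0.66) up.

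Cell division fell in 108 of 308 over that interval, with 11 up and 189 not called (122 and 19 adjusted over the list alone, median -0.30, adjusted p = 1.94e-13). Glucosinolate genes fell in 22 of 67, with 0 up and 45 not called (24 and 0 adjusted over the list alone, median -0.43, adjusted p = 1.51e-12; adjusted p = 0.134 with an estimated correlation), IGMT5 (BnaA07G0364400ZS) by -2.40. In all 8541 genes were called, 5209 higher and 3332 lower, 61.0% higher before rescaling and 44.9% after. With only the 2 groups in the fit 1848 were called, and 5205 without the 2 WT libraries of highest share.

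In bnagrp3 the same interval took AOC2 (BnaC07G0290700ZS) from 12.6 ± 7.13 to 0.98 ± 0.62 TPM (-2.67, adjusted p = 0.0015) and PIP2-1 (BnaA09G0495900ZS) from 336 ± 31.5 to 81.7 ± 6.37 TPM (-2.02, SE 0.11). CYP79B1 (BnaC07G0541500ZS), at the entry to indole glucosinolates, fell from 11.9 ± 4.41 to 0.84 ± 0.33 TPM (-2.75). Jasmonate genes fell in 37 of 104, with 3 up and 64 not called (47 and 12 adjusted over the list alone, median -0.37, adjusted p = 1.63e-10; adjusted p = 0.22 with an estimated correlation), with AOC3 (BnaA09G0228100ZS, 0.71) up. The aquaporin list fell in 28 of 112 genes, with 8 up and 76 not called (31 and 14 adjusted over the list alone, median -0.10, adjusted p = 1.25e-06), with SIP2-1 (BnaA04G0033200ZS, 0.63) up. Glucosinolate genes fell in 24 of 67, with 1 up and 42 not called (30 and 2 adjusted over the list alone, median -0.43, adjusted p = 3.24e-13; adjusted p = 0.127 with an estimated correlation), and SUR1 (BnaA03G0504500ZS, 0.53) rose. In all 8863 genes were called, 5940 higher and 2923 lower, 67.0% higher before rescaling and 45.5% after, and 5456 without bnagrp3 8 h replicate 2. Called genes in either interval were slightly rarer on A than on C chromosomes (odds ratio 0.934, adjusted p = 0.0108, and 0.932, adjusted p = 0.00878), and without the filter on low values the difference was not called (unadjusted Fisher exact p = 0.143 and 0.0528).

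In mock, single copies of photosynthesis, wax and clock genes were lower in bnagrp3. LHCB4.1 (BnaC02G0001800ZS), for a light-harvesting protein, stood at 278 ± 153 TPM in WT and 1.17 ± 0.68 in bnagrp3 (-6.92, SE 0.33, adjusted p = 2.6e-09), and PSAK (BnaA08G0204300ZS) at 744 ± 45.2 and 22.0 ± 3.34 TPM (-5.02). The wax gene CER1 (BnaA09G0698500ZS) stood at 217 ± 42.4 and 17.7 ± 2.40 TPM (-3.53), and KCS1 (BnaA09G0693100ZS) at 24.5 ± 3.35 TPM in WT and listed at 0 in bnagrp3. The clock genes LHY (BnaA10G0008600ZS, 15.4 ± 0.88 against 2.17 ± 0.89 TPM, -2.40) and RVE4 (BnaC03G0011800ZS, -2.34) were also lower. ECS1 (BnaC06G0340100ZS) stood at 1237 ± 296 against 2.22 ± 0.82 TPM (-8.59) and GLP1 (BnaC02G0102600ZS) at 377 ± 58.2 against 0.36 ± 0.62 TPM (-8.20). MCD1 (BnaA10G0109000ZS), for a chloroplast division protein, was higher in bnagrp3, at 26.6 ± 2.24 against 0.02 ± 0.03 TPM (4.75).

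As lists these functions were not called in mock in the main test. Photosynthesis had 40 of 210 genes higher, 27 lower and 143 not called (50 and 31 adjusted over the list alone, median 0.10, adjusted p = 0.0759), with PSAF (BnaC07G0125200ZS, 1.68) higher. It was called higher after median-of-ratios rescaling (0.13, adjusted p = 0.0372) and with the share as a covariate (0.14, adjusted p = 0.0271). Wax, cutin and lipid transfer had 33 of 287 higher, 27 lower and 227 not called, the same adjusted over the list alone; the median was 0.03, the mean -0.01 and the adjusted p 0.398. LTP4 (BnaA02G0105900ZS) stood at 240 ± 16 against 85.7 ± 16.7 TPM (1.49). The circadian clock had 25 of 169 higher, 47 lower and 97 not called (28 and 47 adjusted over the list alone, median -0.03, adjusted p = 0.398), with COR27 (BnaA09G0188300ZS, 1.17) higher.

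The aquaporin list was lower in bnagrp3 mock in 30 of 112 genes and higher in 6, with 76 not called (32 and 7 adjusted over the list alone, median -0.13, adjusted p = 0.0139; adjusted p = 0.248 with an estimated correlation). TIP2-1 (BnaA01G0342600ZS) stood at 44.8 ± 6.21 TPM in WT and 0.05 ± 0.08 in bnagrp3 (-5.45), and PIP2-5 (BnaC08G0347900ZS) at 3.65 ± 0.16 and 8.92 ± 0.91 TPM (1.09). Cytosolic ribosomal protein genes were higher in 297 of 1037 and lower in 69, with 671 not called (366 and 76 adjusted over the list alone, median 0.35, adjusted p = 3.7e-10; adjusted p = 0.438 with an estimated correlation). Leaving out any 1 library moved that median between 0.18 and 0.444. RPS8A (BnaA02G0084900ZS) stood at 19.3 ± 4.01 against 1.59 ± 2.28 TPM (3.31), and RPP1B (BnaC09G0001600ZS) at 0.45 ± 0.42 against 91.1 ± 18.4 TPM (-6.01). The GRP3 list was lower, with 6 of 11 genes down, 1 up and 4 not called, the same adjusted over the list alone (median -0.69, adjusted p = 0.00577; adjusted p = 0.15 with an estimated correlation). With the share as a covariate its median was -0.008 and its call ended (adjusted p = 0.0522). In all 12465 genes were called, 5272 higher and 7193 lower in bnagrp3 (4823 called with the covariate, 30.9% higher), and 4103 differed at least 2-fold. Of the 4823 called with the covariate only 2072 were among the 12465, 1995 of them in the same direction. Called genes were more frequent on A than on C chromosomes (21.9% and 19.3%, odds ratio 1.17, adjusted p = 7.5e-13).

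At 4 h of NaCl LEA14 (BnaC03G0000500ZS) reached 107 ± 38.3 TPM in WT and was listed at 0 in bnagrp3. A desiccation-related gene (BnaA04G0291600ZS) stood at 82.4 ± 31.4 against 3.14 ± 0.64 TPM (-4.26, SE 0.28, adjusted p = 5.4e-08). ERD10 (BnaA07G0133000ZS) was higher in bnagrp3, at 3594 ± 257 against 1828 ± 57.1 TPM (0.97). The jasmonate repressor gene TIFY7 (BnaC02G0251900ZS) stood at 93.4 ± 16.4 against 39.2 ± 19.8 TPM (1.34), and at 0.072 without a call with the share as a covariate (adjusted p = 0.961).

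LEA proteins and dehydrins were lower in bnagrp3 in 31 of 92 genes and higher in 5, with 56 not called (34 and 5 adjusted over the list alone, median -0.35, adjusted p = 0.00135; adjusted p = 0.302 with an estimated correlation). Jasmonate genes were higher in 25 of 104 and lower in 14, with 65 not called (37 and 14 adjusted over the list alone, median 0.36, adjusted p = 0.00139; adjusted p = 0.577 with an estimated correlation), with a further TIFY7 gene (BnaA07G0320600ZS) at 1.33. Ribosomal protein genes were lower in 160 of 1037 and higher in 49, with 828 not called (150 and 45 adjusted over the list alone, median -0.16, adjusted p = 0.0305; adjusted p = 0.767 with an estimated correlation), though RPL13AD (BnaA09G0050200ZS, 2.26) was higher. The aquaporin list was not called (21 higher, 17 lower, 74 not called, 23 and 17 adjusted over the list alone, median -0.03, mean 0.03, adjusted p = 0.584); PIP2-1 (BnaC06G0182600ZS, -2.47) was lower and NIP6-1 (BnaA07G0386200ZS, 1.25) higher. Leaving out 1 library ended the jasmonate call (highest adjusted p = 0.0595), and 2 libraries, each left out alone, ended the ribosomal call (0.0852). With the share as a covariate the LEA (adjusted p = 0.0812) and ribosomal (0.354) calls ended, the jasmonate list turned to -0.19 (0.0931), and estimates turned without a call for BnaA07G0320600ZS (-0.67), BnaA09G0050200ZS (-1.41) and BnaA07G0386200ZS (-0.021). BBD1 (BnaC02G0286800ZS), for a nuclease of plant defence, stood at 291 ± 5.63 TPM in WT and was listed at 0 in bnagrp3. In all 13671 genes were called, 5729 higher and 7942 lower (4401 called with the covariate, 32.7% higher, and 6371 with only these groups in the fit), and 4966 differed at least 2-fold, with more calls on A chromosomes (24% against 20.6%, odds ratio 1.22, adjusted p = 1.5e-19). Of the 4401 called with the covariate 2594 were among the 13671, 2525 of them in the same direction.

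At 8 h LOX2 (BnaC06G0315300ZS), of jasmonate synthesis, was higher in bnagrp3, at 9.33 ± 0.59 against 3.64 ± 0.96 TPM (1.18, SE 0.24, adjusted p = 0.0026), and not called with the share as a covariate (adjusted p = 0.436). TIFY3B (BnaC02G0104800ZS) was listed at 0 in WT and stood at 9.33 ± 3.52 TPM in bnagrp3, while AOC4 (BnaA08G0275600ZS, -1) was lower. TIP2-1 stood at 133 ± 7.26 against 52.1 ± 9.32 TPM for one copy (BnaC01G0423400ZS, 1.34) and 0.03 ± 0.06 against 36.9 ± 5.52 TPM for another (BnaA01G0342600ZS, -5.19). ECP63 (BnaA04G0235800ZS, 1.53) and a LEA gene (BnaC03G0349400ZS, 172 ± 7.68 against 51.8 ± 28.8 TPM, 1.89) were higher. With the covariate AOC4 (0.085), ECP63 (-0.93) and the LEA gene (-0.34) turned direction without a call.

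The jasmonate list was higher in 29 of 104 genes and lower in 8, with 67 not called (33 and 9 adjusted over the list alone, median 0.28, adjusted p = 0.00303; adjusted p = 0.6 with an estimated correlation). With the share as a covariate it was called lower at 8 h (-0.27, adjusted p = 0.00393) and in mock (-0.54, adjusted p = 3.14e-07) (-0.01, adjusted p = 0.981 in the main test), from extrapolated estimates. Not called at 8 h were LEA proteins and dehydrins (14 higher, 9 lower, 69 not called, the same adjusted over the list alone, median -0.09, adjusted p = 0.644) and aquaporins (24, 12 and 76, with 24 and 14 adjusted over the list alone, median 0.14, adjusted p = 0.118). Ribosomal protein genes had 89 higher, 118 lower and 830 not called (83 and 110 adjusted over the list alone); their median was 0.01, their mean -0.05 and the adjusted p 0.975. RPP1B (BnaA09G0018900ZS) was higher at 53.0 ± 5.63 against 6.54 ± 7.18 TPM (3.55, SE 1), and turned without a call with the covariate (-2.52). METTL7A (BnaC06G0360100ZS) stood at 1.13 ± 1.28 against 532 ± 143 TPM (-8.12), and MAP2B (BnaC02G0350700ZS) was listed at 0 in WT and stood at 60.1 ± 26.2 TPM in bnagrp3. In all 13572 genes were called, 6626 higher and 6946 lower (48.8% higher, and 50.4% after quantile normalisation), and 5589 differed at least 2-fold (23.6% of A and 20.2% of C genes called, odds ratio 1.22, adjusted p = 1.5e-19). With the covariate 3497 were called (32.5% higher). Of these 1904 were among the 13572, 1740 of them in the same direction.

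Averaged over the 3 conditions, 23681 genes differed between genotypes, 11201 higher and 12480 lower in bnagrp3 (47.3% higher, and 51% after median-of-ratios rescaling), and 5205 at least 2-fold. With the share as a covariate 4626 were called (30.7% higher), and 15486 with a filter of 5 TPM. Of the 4626, 3234 were also called without the covariate, 2533 of them in the same direction. MCD1 (BnaA10G0109000ZS, 5.32, SE 0.07) was among the largest rises. BnaA10G0298800ZS, of unknown function, stood at 579 ± 43.8 TPM in WT mock and 0.27 ± 0.47 in bnagrp3 mock (-8.96 on average). A metallothionein-like gene (BnaC02G0005000ZS) stood at 193 ± 42.7 to 319 ± 94.9 TPM in WT and was listed at 0 in all bnagrp3 groups. Called genes made up 42.2% of A and 36.7% of C genes (odds ratio 1.26, adjusted p = 8.8e-36, from a Fisher exact test that treats genes as independent). Since 1 mutant line was sampled, a difference fixed in that line's background cannot be separated from the mutation.

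The responses to 4 h of NaCl differed between genotypes in single genes for dehydrins, wall enzymes and an aquaporin. RAB18 (BnaC02G0556300ZS) rose less in bnagrp3, to 308 ± 115 against 1598 ± 362 TPM from similar mock levels (difference of response -2.35, SE 0.40, adjusted p = 0.00737). LEA14 (BnaC03G0000500ZS) rose to 107 ± 38.3 TPM in WT and stayed listed at 0 in bnagrp3 (adjusted p = 3.1e-08), and so did EXLB1 (BnaA03G0438000ZS), at 14.5 ± 4.77 TPM in WT (adjusted p = 2.56e-06). For genes that stay at 0 the test cannot tell a changed response from a copy not detected in bnagrp3. XTH6 fell less in bnagrp3 from a lower mock level (BnaA06G0306600ZS, 77.2 ± 8.26 to 38.8 ± 5.85 against 207.9 ± 14.7 to 43.5 ± 0.87 TPM, difference 1.25), while XTH32 (BnaA05G0083700ZS) fell more (-1.54). Plasma-membrane aquaporin gene PIP2-2 (BnaA03G0177700ZS) went from 8.95 ± 1.99 to 35.9 ± 7.59 TPM in bnagrp3 and from 21.7 ± 4.42 to 23.0 ± 3.83 TPM in WT (1.81, SE 0.27, adjusted p = 0.00332).

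LEA proteins and dehydrins responded less in bnagrp3 at 4 h: 10 of 92 genes had a lower response, 0 a higher one and 82 were not called (19 and 2 adjusted over the list alone, median -0.27, adjusted p = 6e-05; adjusted p = 0.207 with an estimated correlation). The aquaporin list responded more, with 9 of 112 genes higher, 1 lower and 102 not called (28 and 4 adjusted over the list alone, median 0.14, adjusted p = 3.76e-05; adjusted p = 0.0832 with an estimated correlation); PIP2-5 (BnaC08G0347900ZS, -1.16) was the 1 lower. The 85 genes matched by product name had a median of 0.29 (adjusted p = 2.87e-06). Ribosomal protein genes had 79 of 1037 lower, 3 higher and 955 not called (274 and 8 adjusted over the list alone, median -0.49, adjusted p = 1.31e-22; adjusted p = 0.207 with an estimated correlation). RPS16C (BnaA03G0293600ZS, -1.52) and RPL37B (BnaA05G0168100ZS, -1.48) fell further, and RPS3C (BnaC02G0355500ZS, 1.16) and a gene for an L18a-like protein (BnaC05G0256500ZS, 0.64) rose further.

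Jasmonate genes responded more, with 2 of 104 higher, 0 lower and 102 not called, the same adjusted over the list alone (median 0.28, adjusted p = 0.000106; adjusted p = 0.479 with an estimated correlation); LOX1 (BnaA01G0256800ZS, 0.62, adjusted p = 0.025) was one. Cell wall loosening had 2 of 142 higher, 7 lower and 133 not called (4 and 7 adjusted over the list alone, median -0.14, adjusted p = 0.0232; adjusted p = 0.15 with an estimated correlation), and each of 2 libraries left out ended this call (up to 0.103). Carboxylesterase gene CXE5 (BnaA06G0034600ZS) went from 2.53 ± 0.76 to 196 ± 130 TPM in WT and from 0.02 ± 0.03 to 0.62 ± 0.08 TPM in bnagrp3 (-4.83). In all 1426 genes differed in their 4 h response, 662 higher and 764 lower in bnagrp3, and 668 by at least 2-fold. Leaving out 1 library gave 637 to 2561, and leaving out the 2 WT libraries of highest share 2986. With the covariate there were 3507, and with only these groups in the fit 712 (394 higher, 318 lower).

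At 8 h the response of several aquaporin genes differed between genotypes. PIP2-2 (BnaC03G0208200ZS) went from 42.1 ± 9.10 to 5.90 ± 1.01 TPM in WT and from 10.4 ± 2.22 to 5.56 ± 0.85 TPM in bnagrp3 (1.84, SE 0.24, adjusted p = 0.00164), so the 2 genotypes met at a similar level. A neighbouring PIP2-2 gene (BnaC03G0208300ZS) went from 20.5 ± 2.69 to 4.63 ± 1.67 TPM in WT and from 4.86 ± 1.24 to 9.56 ± 1.66 TPM in bnagrp3 (2.83, adjusted p = 0.0371). PER34 (BnaA06G0161600ZS), for a cell wall peroxidase, fell further in bnagrp3, from 77.4 ± 5.13 to 18.1 ± 2.72 TPM against 118 ± 7.22 to 86.2 ± 12.7 TPM (-1.59, adjusted p = 0.000305). The GRP3 gene Bnascaffold0025G0035900ZS rose by 3.38 more in bnagrp3 (SE 0.52, adjusted p = 0.00476).

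Of 112 genes in the aquaporin list 12 had a higher response in bnagrp3 at 8 h, 1 a lower one and 99 were not called (28 and 2 adjusted over the list alone, median 0.37, adjusted p = 3.95e-09; adjusted p = 0.0245 with an estimated correlation). Of the 85 matched by product name 13 were called (median 0.45, adjusted p = 2.12e-12). The jasmonate list had 2 higher, 0 lower and 102 not called, the same adjusted over the list alone (median 0.27, adjusted p = 0.000106; adjusted p = 0.479 with an estimated correlation). Ribosomal protein genes had 2 higher, 5 lower and 1030 not called (2 and 3 adjusted over the list alone, median -0.35, adjusted p = 1.59e-15, and adjusted p = 0.302 with an estimated correlation), among them RPS29A (BnaA03G0539700ZS, -1.19) and RPL39A (BnaC08G0427500ZS, adjusted p = 0.0377). This list was higher in bnagrp3 mock (median 0.351) and not called between genotypes at 8 h, so its lower response may reflect the start level. ABA signalling had 1 higher, 0 lower and 111 not called, the same adjusted over the list alone (median 0.12, adjusted p = 0.0222; adjusted p = 0.444 with an estimated correlation), and each of 3 libraries left out ended this call (up to 0.0978). The 1 gene was AIP1 (BnaA09G0671000ZS), listed at 0 in bnagrp3 mock and at 47 ± 2.96 TPM at 8 h. Class III peroxidases had 2 of 102 higher, 1 lower and 99 not called (4 and 2 adjusted over the list alone, median 0.28, adjusted p = 0.0118; adjusted p = 0.463 with an estimated correlation), a call that each of 2 libraries left out ended (up to 0.0693). CSLA10 (BnaA07G0112700ZS) rose to 21.5 ± 1.2 TPM in bnagrp3 and 3.78 ± 1.07 in WT (3.19). In all 800 genes differed in their 8 h response, 453 higher and 347 lower, and 465 by at least 2-fold. Leaving out 1 library gave 455 to 1171, leaving out the 2 WT libraries of highest share 1541, and adding the covariate 1510. Shares of called genes did not differ by subgenome at 4 h (odds ratio 1.02, adjusted p = 0.768) or 8 h (1.07, adjusted p = 0.515).

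**Figure D4:**
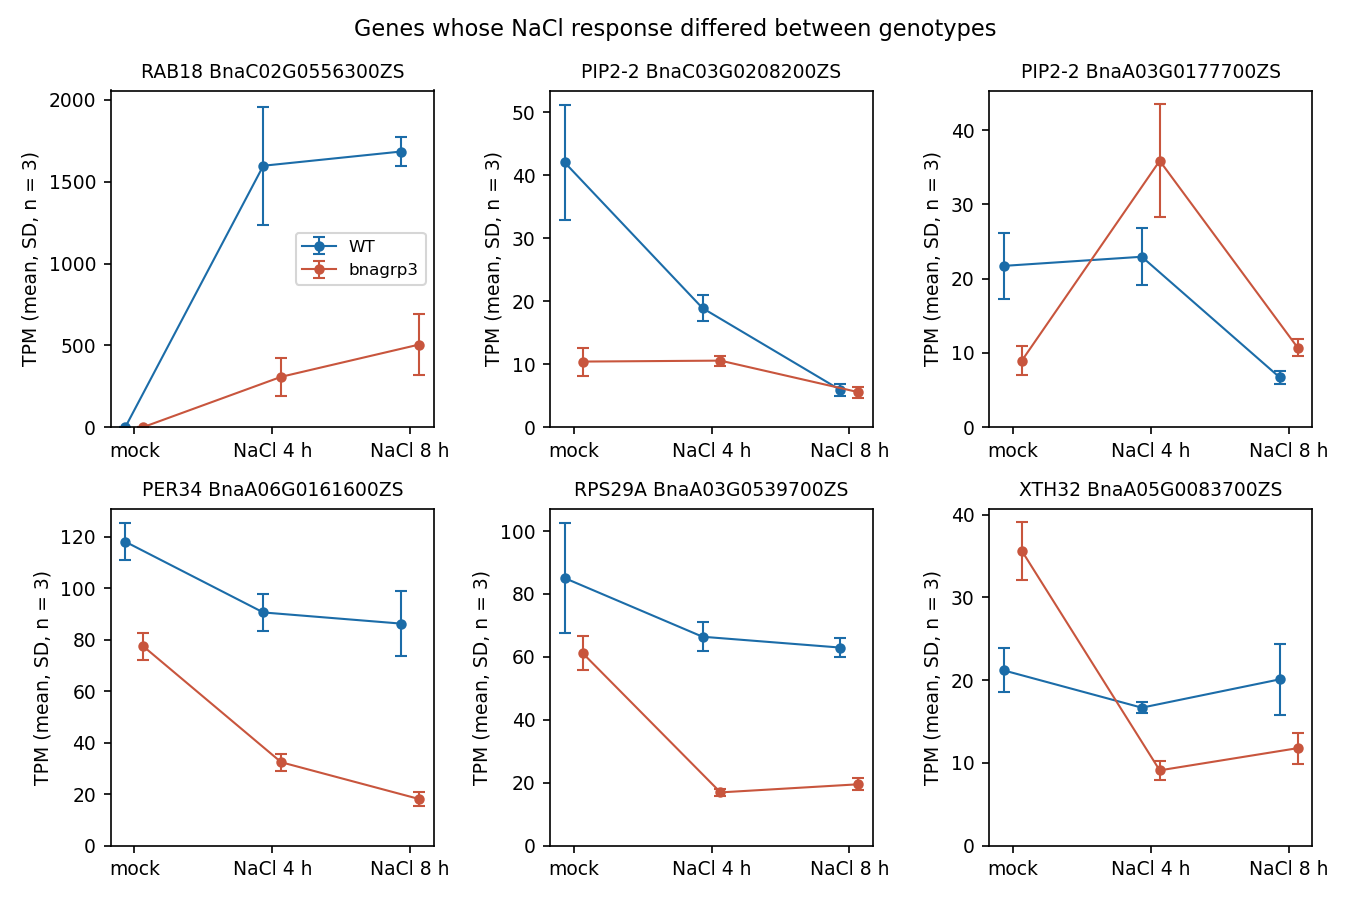
Mean TPM (points, bars are SD, n = 3) of 6 genes in WT and bnagrp3 by treatment. Each passed the test of a difference of response at 4 h or 8 h, and RAB18 at 4 h stands at 1598 TPM in WT and 308 in bnagrp3.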

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

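In this part the tests of mixed RNA, of exchanged labels, of a background that varies among WT libraries and of the mutation alone were chosen only after the results were seen.

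Responses to NaCl differed between the genotypes by the interaction test in 1426 genes at 4 h and 800 at 8 h. At 4 h the lists with a lower response in bnagrp3 were LEA proteins and dehydrins (median -0.27), cytosolic ribosomal proteins (-0.49) and cell wall loosening (-0.14). Photosynthesis (-0.10), wax, cutin and lipid transfer (-0.19) and cell division (-0.20) also had a lower response. None of these lists held with an estimated correlation (adjusted p = 0.15 to 0.609). A higher response at 4 h was seen for jasmonate (0.28), raffinose, trehalose and starch breakdown (0.18), the aquaporin list (0.14) and the circadian clock (0.086). None of these held with an estimated correlation (adjusted p = 0.0832 to 0.479). At 8 h ribosomal proteins (-0.35), heat shock proteins (-0.11), the organelle-type list (-0.10) and cell division (-0.069) had a lower response in bnagrp3. None of them held with an estimated correlation (adjusted p = 0.245 to 0.5). The ribosomal list was higher in bnagrp3 mock (median 0.351) and not called between genotypes at 8 h, so a difference at the start stays open for it. A higher response at 8 h was seen for the aquaporin list (0.37), class III peroxidases (0.28), jasmonate (0.27), raffinose, trehalose and starch breakdown (0.14), the clock (0.12) and ABA signalling (0.12). Of these only the aquaporin list held with an estimated correlation (adjusted p = 0.0245, the others 0.15 to 0.479). Calls for heat shock proteins and for the clock at 8 h ended with any of 12 and of 7 libraries left out (adjusted p up to 0.237 and 0.102), and that for the clock at 4 h with any of 9 (0.119). Organelle and cell division calls at 8 h ended with any of 5 left out (up to 0.16 and 0.0901), and photosynthesis at 4 h with 1 (0.0519).

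Single genes whose 4 h response differed between genotypes were RAB18 (BnaC02G0556300ZS, -2.35), CXE5 (BnaA06G0034600ZS, -4.83), XTH32 (BnaA05G0083700ZS, -1.54), XTH6 (BnaA06G0306600ZS, 1.25, and BnaC03G0517900ZS, 1.24), LOX1 (BnaA01G0256800ZS, 0.62), RPS3C (BnaC02G0355500ZS, 1.16), a gene for an L18a-like protein (BnaC05G0256500ZS, 0.64), RPS16C (BnaA03G0293600ZS, -1.52) and RPL37B (BnaA05G0168100ZS, -1.48). Aquaporin genes were PIP2-2 (BnaA03G0177700ZS, 1.81, and BnaC03G0208200ZS, 1.13) and PIP2-5 (BnaC08G0347900ZS, -1.16). LEA14 (BnaC03G0000500ZS, adjusted p = 3.1e-08) and EXLB1 (BnaA03G0438000ZS, adjusted p = 2.56e-06) were listed at 0 in bnagrp3, so a copy not detected there cannot be told from a changed response. At 8 h they were the GRP3 gene Bnascaffold0025G0035900ZS (3.38), PIP2-2 (BnaC03G0208300ZS, 2.83, and BnaC03G0208200ZS, 1.84), PIP2-5 (BnaC08G0347900ZS, -1.12), PER34 (BnaA06G0161600ZS, -1.59), RPS3C (BnaC02G0355500ZS, 1.19), RPS29A (BnaA03G0539700ZS, -1.19) and CSLA10 (BnaA07G0112700ZS, 3.19). With a group listed at 0 there were AIP1 (BnaA09G0671000ZS, adjusted p = 0.00548), RPL39A (BnaC08G0427500ZS, adjusted p = 0.0377), BnaC08G0459000ZS (adjusted p = 0.014) and LEA14 (BnaC03G0000500ZS, adjusted p = 2.98e-08).

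WT libraries hold bnagrp3-type transcripts in differing shares, from 0 to 0.67. RNA of bnagrp3 mixed into WT libraries would give 1 share on all chromosomes, and in 6 of the 7 WT libraries with a share above 0 the share differed between chromosomes. A permutation test was used, over 184 of the genes that define the share, on 10 chromosomes. In WT 4 h replicate 2 the share ran from 0.22 on A07 (7 genes) to 0.945 on A04 (6 genes), with the smallest p possible (1e-04). The test treats genes as independent, so its p measures no spread between libraries. Exchanged labels would put libraries on the other genotype's side at the GRP3 gene BnaA07G0050000ZS, and 0 of 18 lay there. This gene was chosen once its values were known to differ by label, so the outcome was known when the test was set. Plants of more than 1 genetic type among those labelled WT would make neighbouring genes alike in their profile over libraries, and the mean correlation of 191 neighbouring pairs was 0.128, against 0.004 for pairs on different chromosomes (highest of the permuted orders 0.115, p = 0.001). That explanation stays open, and whether such plants were pooled is not stated.

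Many genes differ between bnagrp3 and WT, 23681 on average. If the mutation alone were responsible, differences among WT libraries would be unrelated to it, but slopes on the share among WT libraries correlated with the genotype difference at 0.422 across 57052 other genes (exact p = 0.00926, 216 orders, highest 0.423). Genes that define the share were picked by their difference between genotypes, so it measures likeness of a WT library to bnagrp3. Some such correlation is thereby built in, and the exact p does not allow for it. The mutation alone is therefore not ruled out. With the share as a covariate 4626 genes were called, 3234 of them called before and 2533 of those in the same direction, but the median SE went from 0.0975 to 0.256 and 63 of 100 orders of the shares within WT groups called as few, so this count decides nothing. The median of the 23681 differences in their first direction went from 0.516 to 0.137, as low in 1 of 100 orders, the real one (median of the others 0.561, lowest 0.138), and 62.9% kept their direction. Since the share is constant in bnagrp3, this change is set by the same slopes among WT libraries as the correlation of 0.422. It is therefore not separate evidence. A genetic background that varies among WT libraries could account for part of the difference, but these values do not decide it. A background fixed in the 1 mutant line stays open and untested.

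The aquaporin list had a higher response in bnagrp3 at 8 h (median difference 0.37). Median-of-ratios rescaling left a median of 0.354. It moved the median of all genes only from 0.02 to 0.003, so it could hardly have removed a median of 0.37. The offset between libraries that it finds is too small to be the source, and other forms of scaling were not tested for this list. A single library as the source was argued against by a lowest median of 0.299 without any 1 library. Adding the share as a covariate left a median of 0.357, but mean shares in WT mock and 8 h lay close (0.233 and 0.179) and 0% of all genes moved by more than their SE, so this decides nothing. A varying background, a difference at the start (several of these genes were lower in bnagrp3 mock) and one in salt response stay open. No biological explanation beyond genotype was tested.

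Other splits of the same samples gave the following. For the 9 comparisons of 3 against 3 libraries, 1 of 10 splits, the real one, called as many genes, and 10 splits are too few for a share under 0.05. The highest other split called 30 (WT 4 h), 15 (WT 8 h), 3 (bnagrp3 4 h), 5 (bnagrp3 8 h), 7 (bnagrp3 8 h against 4 h), 4 (genotype in mock), 12 (genotype at 4 h) and 6 (genotype at 8 h) genes. For WT 8 h against 4 h (8541 genes) it called 2496, setting WT 4 h replicate 1 and WT 8 h replicates 1 and 2, those of lowest share, against the rest, which points to structure among these libraries. For the average genotype difference 1 of 100 splits reached the real count (highest other 341). For the differences of response 8 of 100 (4 h) and 12 of 100 (8 h) did, up to 19174 and 19437 genes, since some splits turn the genotype difference into an interaction. With the average genotype difference removed, 1 of 100 did each time (highest other 5 and 7).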

How the results depend on the processing

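Removal of the 2 WT libraries of highest share, the share covariate and lists matched by product name only were tests chosen after seeing the data; the rest were fixed before. Of 420 values for named genes 362 were called, and 318 to 358 under other settings (343 to 354 with a library left out). TPM keeps no depth, so what depth limits is unknown. A fold threshold of 1 log2 unit left, by its construction, 8877 and 8607 (WT at 4 h and 8 h), 11684 and 9827 (bnagrp3), 1193 and 1310 (8 h against 4 h in WT and bnagrp3), 4103, 4966, 5589 and 5205 (genotype in mock, 4 h, 8 h and on average) and 668 and 465 genes (differences of response at 4 h and 8 h). With only the groups compared in the fit, WT 8 h against 4 h had 1848, genotype at 4 h 6371 and the 4 h difference 712. Counts against mock in WT were 20668 at 4 h and 23171 at 8 h. Fewer samples alone do not account for this, since counts within bnagrp3 rose with as few. They went from 30248 to 30419 at 4 h, from 28782 to 29630 at 8 h and from 8863 to 9334 for 8 h against 4 h. The main fit shares 1 spread per gene over all groups. Mean correlations with the own group were lower for WT libraries (0.912 to 0.953) than for bnagrp3 libraries (0.954 to 0.958). The shared spread may therefore be too small for WT libraries, and main counts that involve them may be too high. A 5 TPM filter, which tests fewer genes, gave 15486 for the average. Without the 2 WT libraries of highest share the counts were 5205 (WT 8 h against 4 h), 2986 and 1541 (differences at 4 h and 8 h). With the share as a covariate they were 4823, 4401, 3497 and 4626 (genotype) and 3507 and 1510 (differences). Called list tests went from 121 to 31 with an estimated correlation. A pseudocount of 0.1 lowered the agreement of WT and bnagrp3 to 0.734 (4 h) and 0.74 (8 h), and of 4 h and 8 h in bnagrp3 to 0.846. A vs C odds ratios became called without a filter in WT at 4 h (1.048) and 8 h (1.043) and bnagrp3 at 4 h (1.054), and with 5 TPM in WT at 8 h (0.95), and lost the call without a filter in WT and bnagrp3 8 h against 4 h (0.9643 and 0.954). The cause was not tested.

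The balance of higher and lower calls turned with rescaling in NaCl comparisons and, with only the groups compared, for the 4 h difference (394 and 318). For NaCl against mock the turn follows largely from rescaling itself, which brings the median of all genes near 0. For the average genotype difference it turned with median-of-ratios rescaling (12166 and 11673) and with quantile normalisation (12470 and 11362). For genotype at 8 h it turned with quantile normalisation (6811 and 6712). At the threshold of 1 log2 unit it turned for 8 h against 4 h in WT (540 and 653) and bnagrp3 (629 and 681). Among named genes and lists, called values turned direction only with the share covariate. In mock these were BnaA03G0387800ZS (0.036), BnaC03G0480300ZS (0.13), BnaA04G0010500ZS (-0.53) and BnaC07G0022400ZS (-1.02). At 4 h they were BnaA07G0320600ZS (-0.67), BnaA07G0386200ZS (-0.021), BnaA09G0018900ZS (-2.097), BnaA09G0050200ZS (-1.41), BnaC03G0349400ZS (-0.067) and the jasmonate list (-0.19). At 8 h they were BnaA03G0387800ZS (0.25), BnaC03G0480300ZS (0.24), BnaA04G0010500ZS (-0.41), BnaA04G0235800ZS (-0.93), BnaA08G0275600ZS (0.085), BnaA09G0018900ZS (-2.515), BnaC03G0349400ZS (-0.34) and the jasmonate list (-0.27, adjusted p = 0.00393). On average they were BnaA03G0387800ZS (0.19) and BnaC03G0480300ZS (0.23). Beyond the effect of rescaling on NaCl against mock, the cause of these turns was not tested.

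Leaving out 1 library gave 23594 to 27074 (WT 4 h), 23722 to 28053 (WT 8 h), 27197 to 31189 and 25423 to 29768 (bnagrp3), 5695 to 9242 and 5456 to 9871 (8 h against 4 h), 9151 to 14021, 9310 to 16918, 9458 to 14958 and 22090 to 24739 (genotype), 637 to 2561 and 455 to 1171 genes (differences), 117 to 130 lists, 6 to 7 GRP3 genes, and agreement of 0.785 to 0.827, 0.786 to 0.823, 0.811 to 0.87 and 0.864 to 0.887. The low ends for the differences came without bnagrp3 mock replicate 2, the high ends without WT 4 h replicate 2. A replicate block kept every count within 1.5 times (26763, 26599, 29947, 28434, 8163, 8541, 12118, 13203, 13157, 23501, 1304 and 655, in the order above), and 0 of 45 pairs with the same number correlated above 0.1.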

Other observations

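Transcripts near 0 in all bnagrp3 libraries were also uneven among WT libraries. A set of 596 genes, chosen after values were seen, lay at or under 0.2 TPM in all 9 bnagrp3 libraries and reached 5 TPM in 2 or more WT libraries. Their median was 4.24, 4.26 and 4.98 TPM in the WT mock libraries, 7.72, 3.8 and 6.72 at 4 h and 6.58, 7.76 and 5.69 at 8 h, in replicates 1, 2 and 3. It was lowest in the library of highest share and highest in the 2 with a share of 0, but mock libraries stood below WT 8 h replicate 3 with its higher share. The choice by 5 TPM in WT bears on these values. Of these genes 51 lie on C03 and 41 on A09. A gene without a known product (BnaC04G0180100ZS) was seen at 28.8 ± 0.25 TPM in bnagrp3 mock and listed at 0 in all other groups.

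Libraries of the mock groups held 11.9% to 13.1% of their TPM in their 20 most abundant genes, and libraries in NaCl 7.56% to 8.92%.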
